A study of Mus musculus with 3 samples.

How the data were processed

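Single cells of mouse sciatic nerve were profiled with Drop-seq, a droplet method in which each captured transcript carries a cell barcode and a unique molecular identifier (UMI). Per the labels, nerves of adult mice were digested enzymatically (collagenase and trypsin), after which cells were either passed through myelin removal beads or sorted by FACS. The series holds 3 samples, 1 per group: injured nerve processed with beads (CD1 mice), injured nerve sorted by FACS (CD1 and C57BL/6 mice, gate not given in the sources used here) and uninjured nerve processed with beads (CD1 mice, cells the authors predicted to be mesenchymal). The injured samples are distal segments taken 9 days after resection. Sequencing batch and date are not given in the sources used here.

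The authors deposited 4 tables of counts, whole-number UMI counts per gene and cell with no normalization: all barcodes of each injured library, and mesenchymal cells alone for the injured and the uninjured beads libraries. The genome build is mm10, per the submitters' processing notes, and the aligner, the counting tool and the authors' rule for mesenchymal cells are not given in the sources used here. Each of the 1289 barcodes of the authors' injured mesenchymal table was found in the injured beads table, with 0 differing counts. Each table lists the genes seen in its own library, and 16095 genes have values in all 3 libraries. A gene missing from the uninjured table was counted as 0, while a gene missing from the FACS table, which lacks several abundant genes, was given no value there. In each table, 5 older gene symbols were replaced by current ones. Gene positions are from GENCODE release vM21, built on GRCm38, the assembly that mm10 names. A single position was found for each of the 39 gene symbols looked up, 2 of them through a synonym in the RefSeq table of GRCm38.

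Computation used Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for 2 other scalings. In the injured tables, barcodes with at least 200 genes were kept. Scrublet, run at an expected rate of 0.05, called 3 of 4111 cells (0.073%) and 9 of 1914 cells (0.47%) doublets, which were removed. A caller that marks so few cells has not worked, so doublets remain in the data. Counts were scaled per cell, log-transformed, reduced to 2000 variable genes and 30 principal components, and clustered by the Leiden method with 15 neighbours at resolution 0.8.

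Clusters were named "-like" from 13 lists of cell type markers and 4 lists of mesenchymal subclass markers. The lists were fixed before the data were examined, as were the groups, the comparisons and the rules for naming genes, but the scoring rule was set afterwards. A name needed the highest mean log2 enrichment over the lower quartile of clusters (with 10 CPM added), a score of at least 1 and a margin of 1 over the next class, 3 markers each seen in 5% of cells, and no more markers of another class than of its own among the 10 leading genes. A cluster with a median UMI count under 1/3 of its library's and no own marker among those genes also stayed unnamed. Macrophage and dendritic cell lists were joined as mononuclear phagocytes after the data were seen. Injured and uninjured mesenchymal cells were clustered together. Subclass sizes were also taken from a clustering that left out the subclass markers.

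With 1 library per group no test was possible, and no p-value is given. Counts were summed over the cells of a pool and expressed as CPM (UMIs of a gene scaled to a pool total of 1e6). Ratios carry an exact conditional binomial 95% interval, CPM values an exact Poisson interval and shares an exact binomial interval, and all of these cover counting error only. They leave out differences between animals, and cells were not treated as replicates. A gene passed the fixed rule of size if a pool had at least 50 CPM, the ratio was at least 2-fold and the interval excluded 1. For a pool at 0 the fold was taken against 3 counts over the pool. It is a lower bound of the observed ratio, not of the interval. Each of 23 lists (18 gene groups, the 4 subclass lists and 1 list of immediate early and dissociation stress genes) was described by the median log2 ratio of members with at least 10 CPM and its percentile among 10000 random lists matched on mean expression. A list at or beyond the outer 2.5 percent on either side is said to stand apart. Named genes were the 12 highest and 12 lowest log2 ratios among genes past the rule that also lay at least 2-fold the same way in the FACS library's mesenchymal-like cells. Mitochondrial, ribosomal, haemoglobin and predicted genes and markers of other cell types were left out. Between the injured libraries the 5 highest and 5 lowest genes are named. Examples of a list were its extreme members and those past the rule, and ligands those of at least 50 CPM in their highest class.

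The size rule was tested on simulated pools of the injured against uninjured comparison, with 3318 genes past the floor. It recovered 2 of 50 genes changed 1.5-fold (4.0%), 19 of 50 changed 2-fold (38.0%), 46 of 50 changed 4-fold (92.0%) and 50 of 50 changed 8-fold, and called 0 of 3123 unchanged genes. The interval held the true ratio for 94.9% of unchanged genes. These pools were drawn at full depth with counting error alone. The values therefore say nothing of differences between cells, animals or libraries, or of the shallower subclass pools. A planted list of 20 genes raised 2-fold reached percentile 100 and an unchanged list percentile 31.7.

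Alternatives covered scaling (DESeq2 size factors, edgeR TMM), the mean of each cell's CPM, cells thinned to 1000 UMIs, floors of 10 CPM and of none, cycling cells left out, cells with at least 2 markers of another class left out, the FACS library as the injured one, resolutions of 0.4 and 1.6, a minimum of 500 genes, doublet calls kept, subclass by highest marker score, and the authors' injured cells against FACS. Alternatives chosen after seeing the data left out cells of unnamed clusters, gave 3 subclasses the same weight, left out the highest 5% of doublet scores, and clustered without subclass markers. Thinning left out 315 injured, 119 uninjured and 45 FACS cells. Values of a few single genes are not reported here.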

Results

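Drop-seq counts were examined for 3 libraries of adult mouse sciatic nerve, 2 from the distal segment 9 days after resection and 1 from uninjured nerve. The injured beads library held 4300 barcodes with 10859939 UMIs (median 1343 per barcode) and the injured FACS library 2000 barcodes with 7122377 UMIs (median 2356.5). The authors' mesenchymal cells numbered 1289 in the injured beads library (4746263 UMIs, median 2798 per cell) and 880 in the uninjured library (2169121 UMIs, median 2102.5). Each group is 1 library, so no difference below has a replicate check, and ranges in brackets are 95% intervals covering counting error only. The series title concerns mesenchymal precursor cells of adult nerve and tissue repair.

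The first comparison asked which cell classes the injured distal nerve held under each isolation. Mesenchymal-like cells were the most frequent named class of the beads library, with 959 of 4108 cells (23.3%, 22.1 to 24.7). Mononuclear phagocyte-like cells were the most frequent class of the FACS library, with 739 of 1905 cells (38.8%, 36.6 to 41.0), followed by 664 mesenchymal-like cells (34.9%, 32.7 to 37.0). In the beads library, endothelial cell-like cells made up 13.9% (12.9 to 15.05), mononuclear phagocyte-like cells 12.4% (11.4 to 13.5) and Schwann cell-like cells 11.4% (10.4 to 12.4). The FACS library held 82 Schwann cell-like and 82 endothelial cell-like cells (4.30% each, 3.44 to 5.32). B cell-like cells (9.47%, 8.59 to 10.4), pericyte or smooth muscle cell-like cells (6.74%, 5.99 to 7.55) and T or NK cell-like cells (5.14%, 4.48 to 5.86) of the beads library had no named cluster in the FACS library, although 16 cells (0.840%) there were named pericyte or smooth muscle cell-like at resolution 1.6. The FACS table has no values for the B cell genes Ms4a1 and Igkc, and its 302 cells of unnamed clusters may hold any of these classes. Neutrophil-like cells made up 3.02% (2.52 to 3.59) of the beads library and 0.840% (0.481 to 1.36) of the FACS library, and mast cell-like cells 0.876% and 1.05%. Strain, isolation and the sorting gate differ together between the libraries. The shares depend on depth too, since unnamed clusters held 13.7% and 15.9% of cells at median UMI counts of 596 and 459. With at least 500 genes per cell the phagocyte-like share of the beads library was 4.82%. That setting also left 441 deeper cells (median 1640 UMIs) in unnamed clusters. Whether cells left out or names lost lowered the share cannot be told apart.

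**Figure D1:**
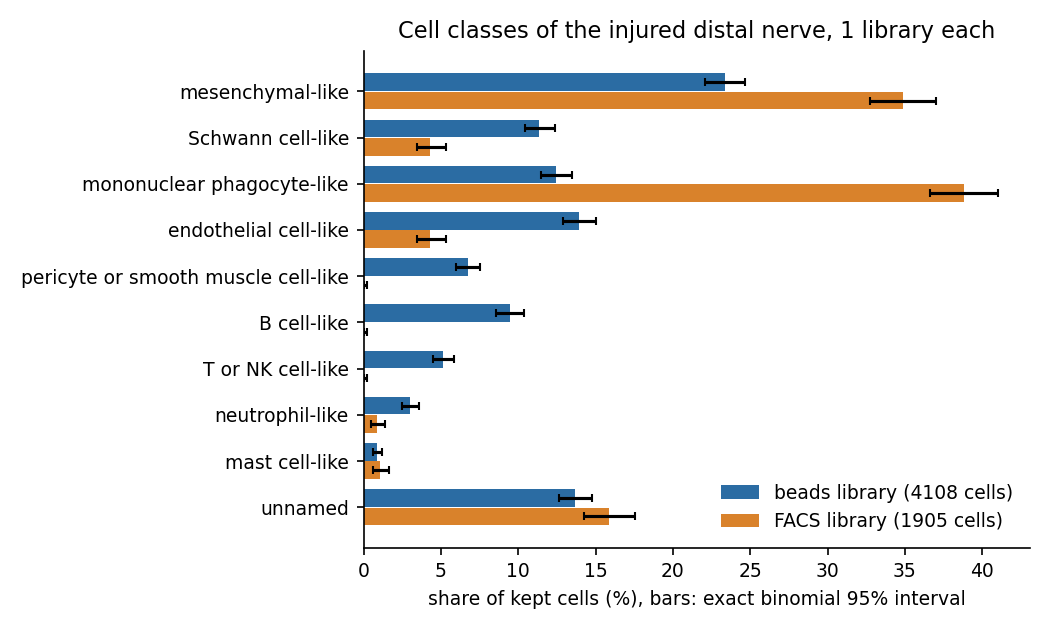
Share of kept cells (x axis, percent) in each named cell class (y axis) of the injured distal nerve, in the beads library (4108 cells) and the FACS library (1905 cells), with exact binomial 95% intervals as bars. Mesenchymal-like cells make up 23.3% and 34.9%, and mononuclear phagocyte-like cells 12.4% and 38.8%.

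The authors' mesenchymal table took in 922 of the 959 mesenchymal-like cells (96.1%), 347 of the 561 cells of unnamed clusters and 6 of the 467 Schwann cell-like cells. Its 1289 cells are 29.98% of the deposited barcodes of that library.

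The next comparison asked which mesenchymal populations of uninjured nerve were found after injury. Clustered without the subclass markers, differentiating-like cells, named from markers that include Dlk1, Mest, Postn and Tnc, were 414 of 1289 injured cells (32.1%, 29.6 to 34.7) and 1 of 880 uninjured cells (0.114%, 0.00288 to 0.631). Endoneurial-like cells were 252 injured cells (19.6%, 17.4 to 21.8) and 428 uninjured cells (48.6%, 45.3 to 52.0), and epineurial-like cells 196 (15.2%, 13.3 to 17.3) and 381 (43.3%, 40.0 to 46.6). Perineurial-like cells had overlapping intervals, with 76 injured cells (5.90%, 4.67 to 7.32) and 67 uninjured cells (7.61%, 5.95 to 9.57). Unnamed clusters held 351 injured cells (27.2%) and 3 uninjured cells (0.341%). In the FACS library, with the markers kept, 156 of 664 mesenchymal-like cells were differentiating-like (23.5%), 84 endoneurial-like (12.7%) and 228 epineurial-like (34.3%), and no cluster was named perineurial-like until cells were thinned, when 18.4% were. By marker score 20.5% of FACS, 14.0% of injured and 14.5% of uninjured cells were perineurial-like. That score gave every cell a subclass, with no minimum, so these shares do not by themselves show that such cells were present. The perineurial-like markers were lower in FACS mesenchymal-like than in uninjured cells (5 of 12 lower, 0 higher, median log2 ratio -1.32). At resolution 0.4 no FACS cell was named differentiating-like, 14.5% were epineurial-like and 72.6% unnamed, and at resolution 1.6 the differentiating-like share was 17.9%. Differentiating-like and injured endoneurial-like cells lay in clusters almost wholly of 1 library, and a cluster mostly of 1 library may be that library, not a type. In the injured library the differentiating-like share was 51.7% at resolution 0.4, 49.9% with thinned cells and 43.3% by marker score.

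**Figure D2:**
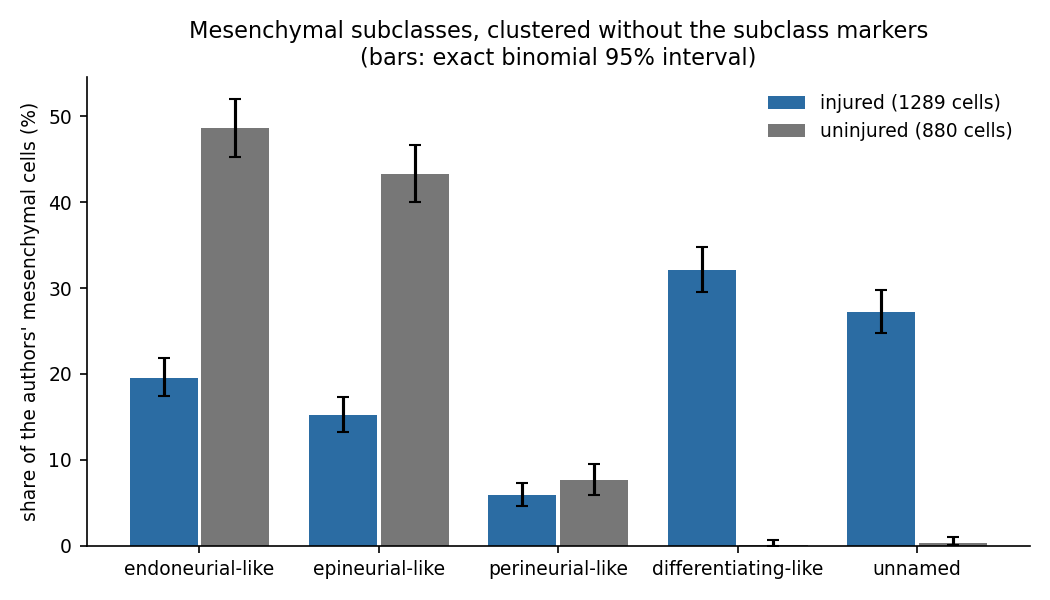
Share of the authors' mesenchymal cells (y axis, percent) in each subclass (x axis), for 1289 injured and 880 uninjured cells clustered without the subclass markers, with exact binomial 95% intervals as bars. Differentiating-like cells make up 32.1% of injured and 0.114% of uninjured cells, and endoneurial-like cells 19.6% and 48.6%.

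Injured and uninjured mesenchymal cells were then compared gene by gene. Tnc, Wif1 and Saa3 were among the genes with the highest ratios, and Myoc, Sc4mol and Enpp2 among those with the lowest. Of 3964 genes past the floor, 324 were higher and 283 lower in injured cells by the fixed rule of size. Tnc, encoding the matrix glycoprotein tenascin C, had 958 CPM in injured and 6.45 CPM in uninjured cells (log2 ratio 7.21, 6.47 to 8.09). Wif1, a secreted inhibitor of Wnt signalling, had 844 and 6.92 CPM (log2 6.93, 6.21 to 7.77). Saa3, an acute-phase serum amyloid gene, had 231 CPM, while the uninjured table has no row for it, which was read as 0 UMIs. Taken against the floor of 3 counts it was 167-fold higher, with a lower interval limit of 136-fold and no upper limit.

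Other named genes higher in injured cells were Cxcl5, a chemokine that attracts neutrophils (log2 6.39, 5.16 to 8.02), the fibrillin gene Fbn2 (369.6 and 11.5 CPM), the angiotensin II receptor gene Agtr2 (5.51, 4.15 to 7.40), and the adhesion genes Chl1 (4.65, 3.89 to 5.53) and Emb (4.56, 3.91 to 5.30). Kng1, encoding kininogen, rests on 2 uninjured UMIs (log2 6.75, 4.89 to 9.80), and its reads may be shared with the near-identical Kng2. The proliferation genes Mki67 (log2 5.01), Top2a (4.97) and Prc1 (4.82) had log2 ratios of 1.19, 3.10 and 2.00 without cycling cells. In another cell class of the injured nerve, Tnc reached 2212 CPM and Chl1 278 CPM (Schwann cell-like), Saa3 1034 CPM (neutrophil-like), Emb 941 CPM and Prc1 105 CPM (T or NK cell-like), and Mki67 572 CPM and Top2a 371 CPM (B cell-like). Tnc is also a marker of differentiating-like cells, and with 3 subclasses at the same weight its log2 ratio was 2.43, that of Saa3 4.48, of Cxcl5 4.14 and of Kng1 4.06, and Agtr2 was near the 2-fold limit.

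Among genes lower in injured cells was Sc4mol, now Msmo1, an enzyme of cholesterol synthesis (9.48 and 184 CPM, log2 -4.28, -4.76 to -3.83). The sterol regulator Insig1 (-3.89, -4.45 to -3.36) and the sterol carrier Stard4 (-3.78, -4.56 to -3.07) were also lower. Angptl7, an angiopoietin-like secreted factor, had 128 CPM in injured and 2240 CPM in uninjured cells (log2 -4.13, -4.25 to -4.01). Myoc, encoding myocilin, had 26.3 and 565 CPM (log2 -4.42, -4.70 to -4.16), and Enpp2, which encodes autotaxin, 39.8 and 746 CPM (log2 -4.23, -4.45 to -4.01). Crispld2 (log2 -4.03), the growth factor gene Bmp4 (-3.72), the transcription factor gene Hlf (-3.54) and the small nucleolar RNA Snord13 (-4.04) were lower too. At the same weight for 3 subclasses the log2 ratio of Myoc was -2.43, of Hlf -2.05, of Bmp4 -2.49, of Stard4 -2.74, of Crispld2 -2.77, of Insig1 -3.04, of Angptl7 -3.10 and of Enpp2 -3.50. Within epineurial-like cells alone many of these ratios were smaller, at -1.48 for Bmp4, -0.95 for Enpp2, -0.94 for Angptl7, -0.88 for Myoc and -0.86 for Crispld2. With few counts there, the intervals held 0 for Sc4mol (-0.24, -1.53 to 0.91), Insig1 (-0.36, -1.64 to 0.78) and Hlf (-0.83, -2.87 to 0.80). Stard4 was at -2.64 there, and Snord13 stayed at -4.02 (-7.09 to -2.12).

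On GRCm38, Tnc lies on chromosome 4 from 63959785 to 64047015 (minus strand), Wif1 on chromosome 10 from 121033960 to 121100650 (plus strand) and Saa3 on chromosome 7 from 46711998 to 46715700 (minus strand). Cxcl5 lies on chromosome 5 from 90759360 to 90761624 (plus strand), Myoc on chromosome 1 from 162639155 to 162649693 (plus strand) and Angptl7 on chromosome 4 from 148495183 to 148500460 (minus strand). All are annotated as protein-coding genes, and the counts are per gene, not per exon.

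**Figure D3:**
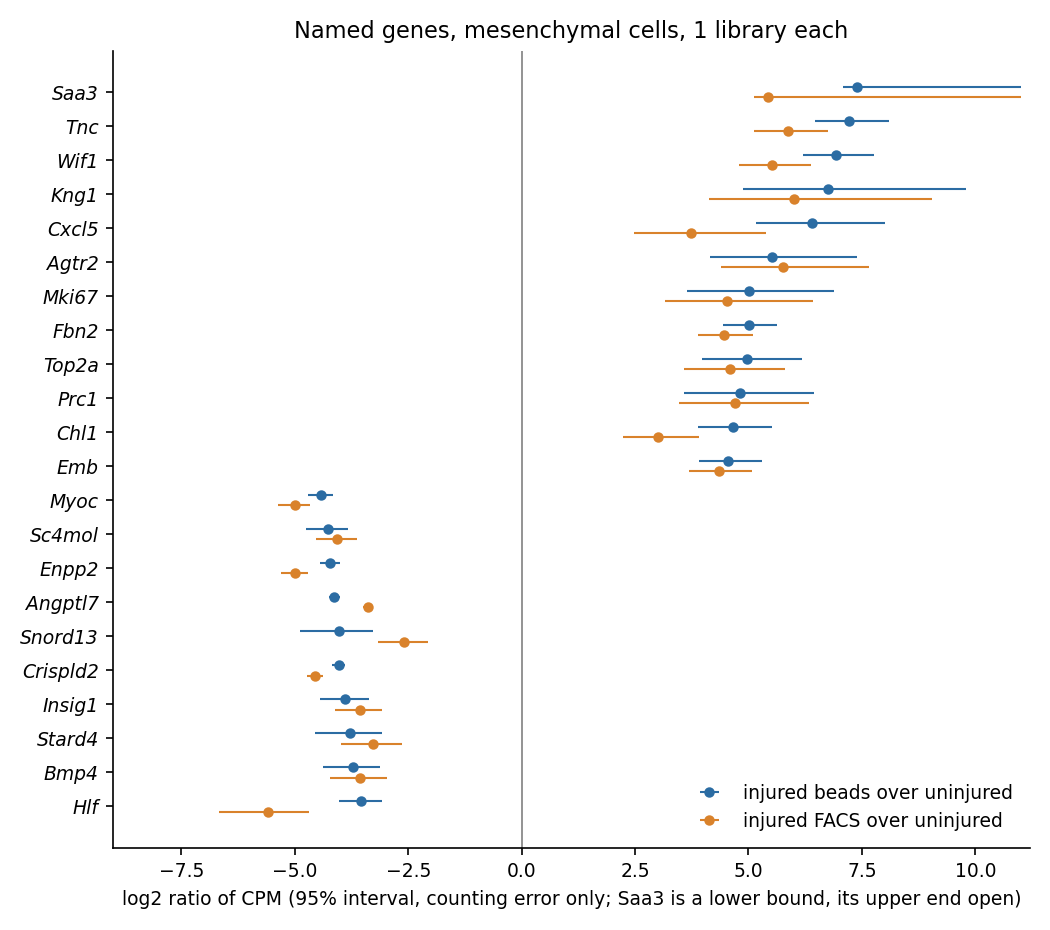
Log2 ratio of CPM (x axis) of named genes (y axis) in mesenchymal cells, for the injured beads library and the injured FACS library, each over the uninjured library, with 95% counting intervals as lines. Tnc lies at 7.21 and 5.88 and Myoc at -4.42 and -5.01, and the Saa3 points are lower bounds of the observed ratios, not of their intervals.

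The FACS library, compared with the same uninjured cells, gave 193 of the genes higher by the size rule in both comparisons and 223 of those lower, among 3690 genes past the floor in both. Unchanged libraries simulated 100 times with counting error alone shared 0 on average in either direction, and independent lists would share 24.97 and 24.81. The simulation leaves out differences between libraries and the independent lists leave out the uninjured library that both comparisons use, so the numbers above either value do not show a shared effect. DESeq2 size factors, which move the median of all genes by -0.12 log2, gave 257 higher and 346 lower genes, and TMM (-0.13 log2) gave 252 and 349. Given the same weight for 3 subclasses, an alternative chosen after seeing the data, 282 genes were higher and 229 lower, of which 132 and 111 were among those above.

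Among groups of genes, ligands for neurons, collagen processing and cell cycle stood apart upwards, and immediate early and quiescent fibroblast genes downwards. Of 10 measured neurotrophic ligands 4 were higher and 0 lower, with a median log2 ratio of 1.69 above all random lists (percentile 100), and of 0.80 (percentile 99) when cells with markers of other classes were left out. These were the growth factor genes Ptn (586 and 51.2 CPM, log2 3.52, 3.24 to 3.80), Mdk (710 and 68.7 CPM, log2 3.37, 3.13 to 3.62), Igf2 (log2 2.66) and Igf1 (2768 and 717 CPM, log2 1.95, 1.87 to 2.03). Of 17 collagen processing genes 5 were higher and 0 lower (median 0.74, percentile 99.98), among them the lysyl hydroxylase gene Plod2 (log2 1.86) and the lysyl oxidase genes Loxl2 (1.15) and Lox (1.02), and with DESeq2 size factors 2 were higher. Of 19 matrix proteases and inhibitors 5 were higher and 1 lower (median 0.52, percentile 99.4), with Timp1 at log2 3.85, Adamts4 at 2.38 and Adamts5 at -1.09. Of 10 osteogenic, chondrogenic and tendon genes 4 were higher and 1 lower (median 1.23, percentile 99.99), with Spp1 at log2 3.23, Runx1 at 2.72 and Comp at -2.99. The last 2 lists did not stand apart when the FACS library stood for injury (medians 0.43 and 0.21), nor collagen processing when the 3 subclasses had the same weight (median 0.17).

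Cell cycle genes had a median log2 ratio of 3.25 over 26 members (percentile 100), with 3 past the rule, namely Mki67, Top2a and Cks1b (log2 1.29). With 3 subclasses at the same weight that median was -0.17, over 9 measured members. The differentiating-like markers were higher for 5 of 6 (median 3.88, percentile 100), with Cthrc1 at 1253 and 65.5 CPM (log2 4.26) and Dlk1 at log2 4.23, and at the same weight for 3 subclasses 2 of 6 were higher (median 0.95). Of 29 collagens and structural matrix genes 9 were higher and 3 lower (median 0.36, percentile 95.5), from Postn at log2 2.83 to Dcn at -1.64 and Fmod at -2.30. Chemokines and cytokines also went both ways, with 5 of 19 higher and 1 lower (median 0.13, percentile 43.7), but at the same weight for 3 subclasses they stood apart upwards (5 higher, 0 lower, median 0.49, percentile 98.9). Ccl2 had 1320.4 CPM in injured and 109 CPM in uninjured cells, and Cxcl2 was at log2 3.43, Ccl7 at 1.04 and Cxcl13 at -2.14. Contractile genes (10 measured, 2 higher, 1 lower, median 0.45, percentile 95.2), IGF binding proteins (5, 1 and 1, 0.75, 97.46), MHC class I and interferon genes (10, 0 and 0, 0.45, 91.4) and glycolysis genes (11, 0 and 0, 0.30, 80.3) did not stand apart. With the FACS library as the injured one, glycolysis genes (4 higher, median 0.81, percentile 99.93) and IGF binding proteins (percentile 97.65) did. So did MHC class I and interferon genes at the same weight for 3 subclasses (percentile 99.05) and without cells holding markers of other classes (percentile 97.52), and the collagens and structural matrix without those cells (percentile 98.72). Examples are Actn1 at log2 1.88, Igfbp4 at 1.43, Igfbp6 at -1.35, Tap1 at 1.11 and Ldha at 0.96.

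Immediate early and dissociation stress genes were lower for 13 of 18 members and higher for 1, with a median of -1.26 below all random lists (percentile 0). Zfp36 was at log2 -1.84, Fos at -1.64 and Junb at -1.63, while Ier3 was at 1.59. Lipid handling and quiescent fibroblast genes were lower for 6 of 18 and higher for 0 (median -0.83, percentile 0), with the actin-severing gelsolin gene Gsn at 2048 and 17373 CPM (log2 -3.08) and the transcription factor gene Klf4 at log2 -1.69. Their median was -1.04 in endoneurial-like and -1.20 in perineurial-like cells, but 0.20 in epineurial-like cells (1 of 18 lower, percentile 92.7). Epineurial-like markers were lower for 5 of 6 (median -1.47, percentile 0.010), including Pcolce2 (log2 -2.50) and Dpp4 (-1.91), and at the same weight for 3 subclasses their median was -0.13. Perineurial-like markers were lower for 2 of 12 (median -0.49, percentile 0.12), Itgb4 at -1.94 and Lypd2 at -1.79, and endoneurial-like markers for 2 of 6 (median -0.21, percentile 9.22) with Osr2 at log2 -1.78, although with FACS as the injured library the latter stood apart downwards (3 lower, median -0.77, percentile 0.54). Of 11 Wnt and BMP antagonists 2 were lower and 1 higher (median -0.85, percentile 0.28), with Sfrp2 at log2 -1.49 against Wif1. Of 28 other growth factor ligands 3 were higher and 2 lower (median -0.19, percentile 0.31), with Angpt1 at log2 1.43 and Gdf10 at 78.4 CPM in injured and 313 CPM in uninjured cells. Of 9 complement genes 2 were lower and 0 higher (median -0.53, percentile 1.64), C1ra at -1.01 and Cd55 at -1.03, and with 3 subclasses at the same weight the median was 0.36. Wnt antagonists (median -0.35) and other growth factor ligands (-0.06) no longer stood apart at that weight, nor did the latter with FACS as the injured library (percentile 10.11) or without cells holding markers of other classes (percentile 4.2).

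Markers of other cell classes differed between the same pools. Macrophage or monocyte markers summed to 303 CPM in injured and 24.4 CPM in uninjured cells, and the macrophage state list was higher (10 measured, 3 higher, 2 lower, median 2.64, percentile 100), with Spp1 at log2 3.23 and Apoe at -1.21. Neutrophil markers summed to 51.2 and 3.23 CPM, beside the higher Saa3 and Cxcl2. Schwann cell markers were lower in injured cells (128 and 390 CPM), beside myelin genes (6 measured, 0 higher, 2 lower, median -1.85, percentile 0), with Pmp22 at log2 -1.61. Repair Schwann cell genes (7 measured, 0 higher, 1 lower) had a median of 0.79 (percentile 98.2), with Jun at log2 -1.46, and they did not stand apart without cells of unnamed clusters (percentile 96.95) and had a median of -0.093 at the same weight for 3 subclasses. Erythroid markers summed to 112 and 1612 CPM, and endothelial markers to 169 and 216 CPM. The pooled markers of pericytes or smooth muscle were at 382 and 455 CPM, of mast cells at 34.3 and 31.8 CPM, of B cells at 10.1 and 1.38 CPM, of T or NK cells at 6.32 and 3.23 CPM and of dendritic cells at 2.74 and 0.461 CPM. Adipocyte markers were at 5.48 and 6.92 CPM and skeletal muscle markers at 8.64 and 16.6 CPM. Mitochondrial transcripts were 1.37% and 1.497% of UMIs and ribosomal protein transcripts 4.11% and 3.39%. Xist was at 472 and 194 CPM and 4 Y-linked genes together at 100.5 and 162 CPM.

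Within subclasses, more genes passed the rule in endoneurial-like cells than in epineurial-like cells, but the clustering and the depth per cell may set that order. Of 3715 genes past the floor, 403 were higher and 352 lower in injured endoneurial-like cells (cluster 0 gave 243 of the injured cells, and cluster 9 all 427 uninjured ones). Clusters part where cells differ, so pools taken from separate clusters were bound to differ. Median UMIs per cell were 6302 injured and 2181 uninjured in endoneurial-like cells, and 1875 and 2019.5 in epineurial-like cells. Epineurial-like cells gave 152 higher and 79 lower genes of 3756, and perineurial-like cells 282 and 368 of 4853. Thinned to 138333 UMIs per pool, the counts were 422 and 339, 193 and 111, and 264 and 334 in that order, while unchanged pools simulated with counting error alone gave 62.9 and 63.8, 62.2 and 61.1, and 73.3 and 68.4. Endoneurial-like cells thus still gave more genes than epineurial-like cells at equal pool depth, but this thinning did not match the depth per cell. In endoneurial-like and epineurial-like cells, 3048 genes were past the floor in both. Of these, 237 and 72 were higher and 245 and 60 lower, in that order. The subclasses shared 28 higher and 25 lower genes, where independent lists would share 5.60 and 4.82. Both subclasses compare the same libraries, so a difference between those libraries could be shared too. The numbers above independent lists therefore do not show a shared response to injury. Timp1 was at log2 5.87 in endoneurial-like cells and Mmp3, a matrix protease, at 6.92. Wif1 was at 7.85 (2278 CPM in injured and 9.89 CPM in uninjured cells). It is itself a marker used to name endoneurial-like clusters, so its ratio there is not independent of the naming.

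Chemokines stood apart in endoneurial-like cells (15 measured, 7 higher, 1 lower, median 1.72, percentile 100), with Ccl2 at log2 4.28 and Cxcl14 at 2.24, beside the macrophage state list (8 measured, 4 higher, 1 lower, median 2.24, percentile 99.97). Complement genes of these cells were higher for 3 of 9 and lower for 0 (median 0.37, percentile 81.7), among them C3 at log2 3.86 and C4b at 2.73, and the list did not stand apart. In epineurial-like cells MHC class I and interferon genes stood apart (12 measured, 2 higher, 0 lower, median 0.79, percentile 99.95), with Psmb8 at log2 1.04, as did the macrophage state list (9 measured, 1 higher, 0 lower, median 0.98, percentile 99.98). Perineurial-like cells had 5 of 28 collagens and structural matrix genes higher and 0 lower (median 0.47, percentile 99.98), with Col5a1 at log2 2.35.

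The 2 injured libraries were set against each other to show how far apart libraries of injured nerve can lie. Of 3930 genes past the floor, 59 were higher and 143 lower in the beads library's mesenchymal-like cells. Sfrp5, a secreted Wnt inhibitor (343 and 54.1 CPM, log2 2.66, 2.46 to 2.87), Cxcl5 (2.61, 2.34 to 2.89), Saa3 (1.96), the deiodinase gene Dio2 (1.93) and A2m (1.73) were higher with beads. Wfdc17 (log2 -2.55), Tyrobp, an adaptor of myeloid cells (-2.50), and Nme2, whose reads may be shared with Nme1 (-2.54), were lower. Macrophage or monocyte markers summed to 1085 CPM in the FACS mesenchymal-like cells, and the macrophage state list was lower with beads (13 measured, 1 higher, 3 lower, median -0.84, percentile 0). Birc5 (-3.13) and Prc1 (-3.02) were lower with beads, as was the cell cycle list (7 of 28 lower, median -2.31, percentile 0), but over the authors' mesenchymal cells the log2 ratios were -0.72 for Birc5 and 0.11 for Prc1. In the clustering of the whole beads library an unnamed cluster held cycling cells, but not all of them. Mki67 was at 572 CPM in B cell-like cells, and at 122 CPM in differentiating-like cells of the mesenchymal clustering. Lists that stood apart upwards with beads, mostly through members short of the rule, were collagens (3 of 29 higher, median 0.42, percentile 99.99), osteogenic, chondrogenic and tendon genes (1 of 10, 0.51, percentile 99.8), chemokines (2 of 19 higher and 1 lower, 0.35, percentile 99.8), and the endoneurial-like (1 of 6, 0.67, percentile 99.9) and perineurial-like markers (0 of 12, 0.59, percentile 99.96). Downwards these were glycolysis (1 of 12 lower, -0.31, percentile 1.59) and repair Schwann cell genes (1 of 8 lower, -0.52, percentile 0.28).

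The last comparison asked which class held the highest level of each ligand in the injured nerve. Mesenchymal-like cells held the highest level of Igf1 in both injured libraries, 2823 CPM (2772 to 2874) with beads and 2215 CPM (2170 to 2260) with FACS, followed by mononuclear phagocyte-like cells (213 and 293 CPM). The same class led for Mdk, at 667 CPM (642 to 692) and 777 CPM (750 to 803), and for Ptn, at 582 CPM (559 to 605) and 784 CPM (757 to 811). Schwann cell-like cells led for Gdnf, a survival factor of motor and sensory neurons, at 117 CPM (98.6 to 139) and 181 CPM (131 to 244). Mesenchymal-like cells had 2 Gdnf UMIs with beads (0.476 CPM) and 0 with FACS. Gdnf lies on GRCm38 chromosome 15 from 7810846 to 7837575 (plus strand) and Igf1 on chromosome 10 from 87858265 to 87937042 (plus strand).

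Schwann cell-like cells also led for the epidermal growth factor family ligand Hbegf, at 520 CPM (480 to 563) and 938 CPM (819 to 1069), and for Clcf1, at 76.3 and 177 CPM. Endothelial cell-like cells led for Kitl (466 and 287 CPM) and Cxcl12 (515 and 671 CPM), and mesenchymal-like cells for Ccl11 (825 and 485 CPM), Cxcl14 (469 and 481 CPM) and Il33 (332 and 315 CPM). Neutrophil-like cells led for Cxcl2, at 32211 CPM (31030 to 33426) and 35922 CPM (32139 to 40027), the latter from 16 cells. Mast cell-like cells, of which there were 36 and 20, led for Ccl2 (2067 and 2640 CPM), followed by mesenchymal-like cells (1490 and 548 CPM). Of 47 ligands past the floor with beads, 11 were highest in mesenchymal-like, 11 in pericyte or smooth muscle cell-like, 7 in endothelial cell-like and 5 in Schwann cell-like cells, and of 38 with FACS, 12 were highest in mesenchymal-like, 8 in endothelial cell-like and 7 in Schwann cell-like cells. Both libraries had 34 of them past the floor, 25 with the same highest class, and for 27 of the 34 that class existed in both libraries.

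**Figure D4:**
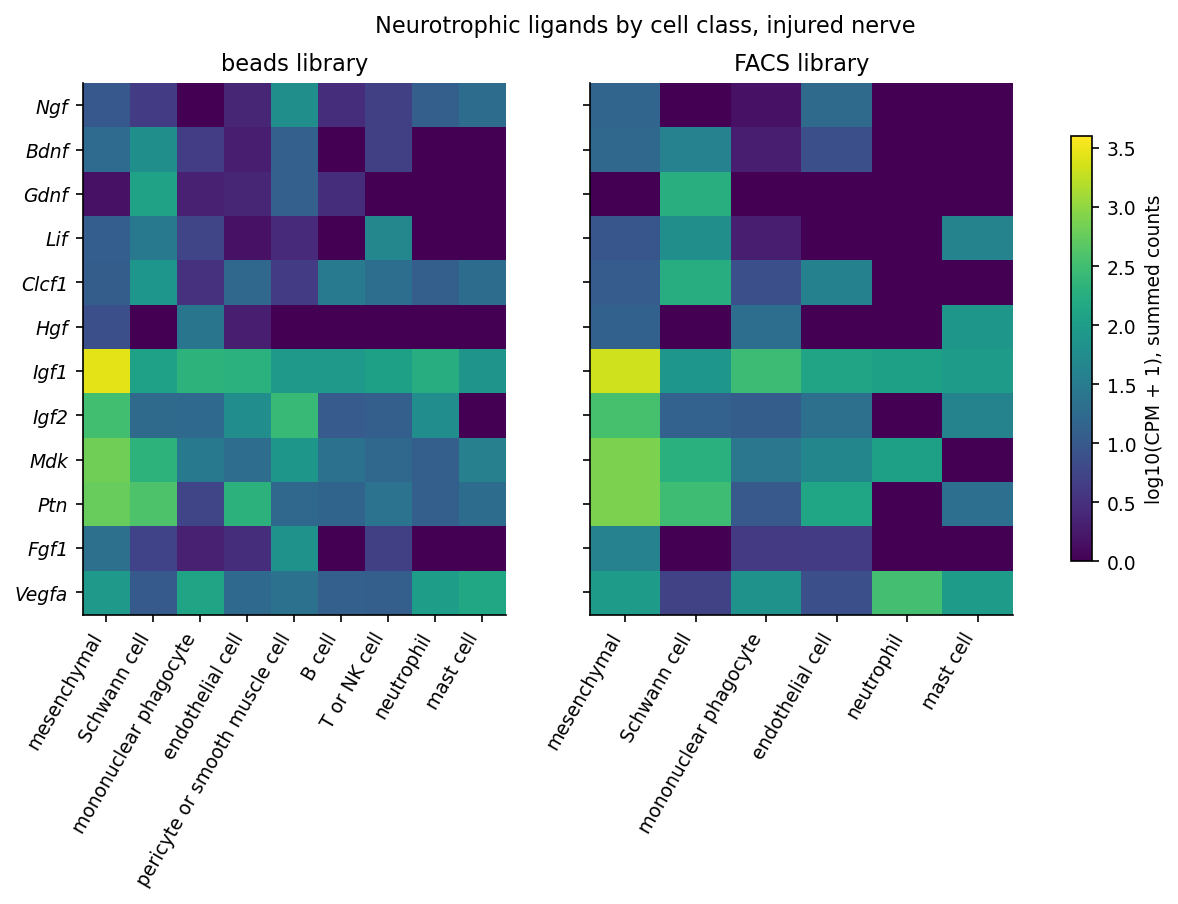
Level of neurotrophic ligands (y axis) in each named cell class (x axis) of the injured beads and FACS libraries, as log10 of CPM + 1 of summed counts on a colour scale. Igf1 is highest in mesenchymal-like cells (2823 and 2215 CPM) and Gdnf in Schwann cell-like cells (117 and 181 CPM).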

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

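The tests of a library-wide shift, of the CPM gain per subclass, of genes chosen and measured on separate UMIs and of the immediate early genes were chosen only after the result was seen. The tests of the unseen cholesterol genes, of Schwann cell RNA and of the level in other classes were not.

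Few genes passed the rule in opposite ways in 2 subclasses of the same libraries, and the difference was not tested. Only 1 was higher in endoneurial-like and lower in epineurial-like cells, and 2 were the reverse. Unchanged epineurial-like pools gave 62.2 higher genes on average from counting error, but at the lower depth of 138333 UMIs. These genes were called at full depth, where the number of such calls was not simulated, so that value cannot be set against them. Their intervals below, which cover counting error only, exclude 0 in both subclasses. Cyr61, a matricellular growth regulator, was at log2 1.91 (1.72 to 2.10) in endoneurial-like cells and -1.10 (-1.45 to -0.76) in epineurial-like cells. Taf7 was at -2.11 (-2.72 to -1.54) and 1.45 (0.51 to 2.40), and Vgll4 at -1.14 (-1.70 to -0.59) and 1.13 (0.38 to 1.87). The other growth factor and morphogen ligands had medians of 0.44 and -0.16. Endoneurial-like values compare cluster 0 of the injured library with cluster 9 of the uninjured one.

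Cholesterol genes, a list of 23 made after the first of them had been seen, were lower in injured endoneurial-like cells, at a summed 172 CPM (153 to 194) against 2565 CPM (2472 to 2661), and the 13 members not seen before had a median log2 ratio of -2.88, at percentile 0 of random lists. The measured ones among these were also lower in epineurial-like (median -0.83, percentile 0.41) and perineurial-like cells (-1.41, percentile 0.23) and in the FACS library over the uninjured one (-1.56, percentile 0). A shift of the whole library is argued against as the whole cause of the endoneurial-like values, since the genes of the list differed less in epineurial-like cells, by a median of 3.30 log2 (quartiles 1.53 and 4.19). That size takes in the members seen before. It is also limited by low counts in epineurial-like cells, where 1 injured UMI is 2.48 CPM. The endoneurial-like values compare separate clusters, which were bound to differ, and this could widen the difference. The members not seen before had medians of -2.88 (13 measured) and -0.83 (9 measured) in these subclasses. Schwann cell markers were lower in injured endoneurial-like cells too (80.2 against 486 CPM), but free RNA or doublets of Schwann cells are argued against as the whole cause, since uninjured endoneurial-like cells held 2.90 times (2.43 to 3.47) as many cholesterol UMIs per Schwann marker UMI as epineurial-like cells. A part played by either stays open, as do a difference between the animals or the handling of these libraries and a lower sterol programme after injury, which may be the cause.

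The 403 genes higher in injured endoneurial-like cells had a median log2 ratio of 1.62 there and 0.32 in epineurial-like cells (quartiles -0.04 and 0.79). The test of free RNA written beforehand found a higher CPM in a non-mesenchymal class for 59.3% of these genes (239). That is above the 50 percent it named in favour of free RNA. But it set the highest of several classes against 1 pool, and no share over all genes was taken, so it cannot decide. In a test added after that value was seen, the CPM gain in epineurial-like cells, which free RNA should raise alike, was a median of 0.10 of that in endoneurial-like cells (quartiles -0.01 and 0.35). Because the genes were chosen for their ratio in these cells, 467 genes were also chosen on a random part of the endoneurial-like UMIs and measured on the rest, where the log2 ratio in epineurial-like cells was lower by a median of -1.20 (quartiles -2.13 and -0.54) and the gain was 0.12 (quartiles -0.01 and 0.42). Splitting the UMIs takes away only the counting error of the choice, since both parts come from the same cells and clusters. Separate clusters were bound to differ, so the larger endoneurial-like values cannot decide against a shift of the whole library or free RNA. Either could play a part, as could doublets or a difference between the clusters compared. A response of these cells to injury is a hypothesis that stays open.

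The immediate early list had medians below 0 in the 3 subclasses, of -1.41 in endoneurial-like (15 of 18 lower), -0.83 in epineurial-like (7 lower) and -0.46 in perineurial-like cells (4 lower, 1 higher), a range of 0.95, and of -1.17 in the FACS library. Different handling of the uninjured library could give this, but a biological difference cannot be told apart from it, because injury and library are the same split here.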

How the results depend on the processing

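The alternatives that gave 3 subclasses the same weight, left out unnamed clusters, left out the highest doublet scores or left out subclass markers, and the tests on them, were chosen after seeing the data. No paired analysis was possible because each group is 1 library, the labels share no pairing and no result comes from a test.

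Of the counts and main shares, 76 of 100 values stayed within their limits and 24 moved, with none reversed. A floor of 10 CPM gave 991 higher and 675 lower genes and no floor 1407 and 1094, since more genes were compared. The number of lists standing apart downwards was 4 in place of 8 at the same subclass weight. Mesenchymal-like cells of the beads library were 33.9% at resolution 0.4, 32.3% with at least 500 genes and 25.7% without the highest doublet scores, and of the FACS library 28.6% at resolution 1.6, 25.7% with called doublets kept and 37.3% with at least 500 genes. Schwann cell-like cells with beads were 8.71% at resolution 1.6 and 12.8% with at least 500 genes. Mononuclear phagocyte-like cells were 4.82% with beads at 500 genes, and 35.3% at resolution 1.6 and 42.6% at 500 genes with FACS. Injured endoneurial-like cells were 27.3% at resolution 0.4, 26.6% thinned and 26.2% by marker score, and differentiating-like cells 51.7%, 49.9% and 43.3%. By marker score, uninjured cells were 43.3% endoneurial-like and 1.59% differentiating-like, with 99 injured and 84 uninjured cells within 0.1 of another subclass's score. The 500-gene minimum leaves out shallow cells by construction, but it also changes which clusters are named. The cause of the moves was not tested.

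At the same subclass weight the medians of cell cycle (-0.17, over 9 measured members in place of 26), complement (0.36) and repair Schwann cell genes (-0.093) reversed. Contractile (-0.16) and glycolysis medians (-0.05), of lists that stood apart in neither setting, changed sign too. Prc1 reversed to 0.11 between the injured libraries over the authors' cells. The cause of these changes was not tested. Of the lists, 96 values kept their call, 7 gained one and 9 lost one. Of the values of the 24 named genes 53 of 213 moved, and at the same weight 21 genes had a value. None reversed or came under 2-fold under the alternatives that gave a value, but with FACS as the injured library the choice of these genes fixed that outcome. Other shares moved in 18 of 90 cases, among them neutrophil-like cells, with no named cluster at 500 genes. The highest class of a ligand changed for 3 of 47 with beads by the mean of cells' CPM. Depth limits the smallest pools, where 1 UMI is 109.5 CPM (FACS neutrophil-like), 19.6 and 17.8 CPM (FACS and beads mast cell-like), 11.5 CPM (beads neutrophil-like) and 7.23 CPM (uninjured perineurial-like).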

Other observations

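Beyond the ligand lists compared between libraries, neutrophil-like cells of the injured nerve held the highest levels of Il1b, the gene of interleukin 1 beta (33222 CPM with beads and 16756 CPM with FACS), and of Tnf (1229 and 1095 CPM). Schwann cell-like cells held the highest levels of Btc, an epidermal growth factor family ligand (714 and 959 CPM), and of Shh, the gene of sonic hedgehog (103 and 185 CPM). The next class for Btc had 11.5 CPM with beads and 11.95 CPM with FACS. Mononuclear phagocyte-like cells led for Cxcl16 (410 and 401 CPM) and Ccl8 (178 and 1200 CPM).

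The FACS table has a gene named tdTomato, with 2 UMIs in 2 of 2000 barcodes, 1 in a mononuclear phagocyte-like and 1 in an endothelial cell-like cell. None of the 664 mesenchymal-like cells had one.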
